A study of Rattus norvegicus with 58 samples.

How the data were processed

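Synovial RNA in 58 libraries was analysed, prepared with a stranded total RNA kit and sequenced as single reads of 75 nt, per the labels' protocols. HISAT and DESeq are named in the submitters' processing notes without versions. The aligner settings, genome build and annotation are not given in the sources used here. The deposited values are on a log2 scale, per the file's own values: each is the log2 of a whole number of reads times 1 factor per library, and 0 reads is held as 0.9 of a read. Whole reads were recovered for 100% of the values above 0, within a relative tolerance of 0.001. The factor ran from 1.71 to 17.5 megareads per unit, and reads in genes made up between 24.5% and 49.9% of it. The table had 16880 rows, of which 16879 carried an identifier. The row without an identifier held between 0.000384% and 0.0137% of reads and was left out of totals and tests.

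Groups and replicate numbers came from the sample titles, and no gene in the table serves as a check of which arthritic rats received RTD-1, a peptide. Labels do not state which libraries came from which animal, so p-values measure the spread between these libraries. Within each group every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 2.70. Reads in genes ran from 464693 to 7716834 per library. A library was called deeper where its factor was at least 10 megareads, a limit set after seeing the data, which held for 13 libraries, 10 from healthy RTD-1 rats and 3 from saline rats.

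Recovered reads were scaled to the depth of the median library, with a factor of 5.75 megareads, and called normalized reads. Genes with at least 10 normalized reads in at least 4 libraries were kept, which left 13062. limma 3.58.1 in R 4.3.3 was run on log2(normalized reads + 1), with 1 fit of 10 group means over all libraries and empirical Bayes moderation with trend and robust settings. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called. This test was chosen before the data were examined, for values assumed to be reads divided by size factors. The values proved to be log2, and the same test was applied after undoing the logarithm. Comparisons of RTD-1 day 1, 3 and 5 with untreated PIA, and of both arms at day 5 with naive, were added after the data were seen.

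The arthritis signature was the set of 3219 genes called between PIA and naive with a change of at least 2-fold. A library's score was the mean log2 value of the signature genes higher in PIA minus the mean of those lower, less the naive mean. Arms were compared by two-sided exact permutation tests over all assignments of libraries, adjusted over the 3 days as fixed before the data were examined, with 95% intervals by inverting the test. In comparisons with PIA or naive libraries, which define the signature, each of those libraries was scored with a signature fitted without it. The libraries compared with them kept the full signature. Permutation p-values and intervals of these comparisons are therefore approximate. Differences of effects between days were tested with 100000 permutations of the arm labels within days, on scores centred on the mean of their arm. Centring narrows the permuted spread, so these p-values may be too small.

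Genes to be named were those with the largest folds in PIA against naive among called genes with a mean log2 value of at least 5. The rule fixed beforehand took 8 per direction and needed symbols. The reference table used here paired none of the identifiers with a symbol, so 2 per direction are given by identifier, and the lists of genes and cell markers fixed beforehand were not analysed here. Any other gene named was chosen after its values were seen. On simulated data drawn from these libraries, with 50 genes changed at each fold, the test of PIA against naive recovered 8% of 1.5-fold, 44% of 2-fold and 88% of 4-fold changes over 12677 genes, with 6 false calls. Each simulated gene was drawn independently, around the same mean in all libraries apart from the changes made.

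Alternatives were pseudocounts of 0.5 and 8, no filter and a filter of 50 normalized reads, TMM factors, quantile normalization, only the groups compared in the fit, limma array weights, a replicate block, a term for or restriction to replicates 1 to 4 or 5 to 8, and each library left out in turn. Added after the data were seen were limma voom on recovered reads, reads thinned to at most 1500000 per library, and leaving out the deeper saline libraries. Principal components were computed on median-centred log2 values. Figures were drawn with matplotlib.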

Results

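RNA from synovial tissue of female DA rats was sequenced in 58 libraries that fell into 10 groups. Arthritis had been induced with pristane, a hydrocarbon oil that provokes an autoimmune-like polyarthritis in rats. Arthritic rats (pristane-induced arthritis, PIA) were sampled untreated (n = 4), or after saline for 1 day (n = 4), 3 days (n = 8) or 5 days (n = 8). Matching arthritic rats received RTD-1 for 1 day (n = 4), 3 days (n = 8) or 5 days (n = 8). RTD-1 is rhesus theta-defensin 1, a macrocyclic peptide of the innate immune system, given under the skin at 5 mg per kg. Naive rats (n = 4) and healthy rats given RTD-1 for 3 days (n = 5) or 5 days (n = 5) completed the set, and no healthy group given saline was analysed here. Between 464693 and 7716834 reads per library fell in genes. The shallowest libraries were replicate 6 (464693 reads) and replicate 8 (935255 reads) of the 3-day RTD-1 group.

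Disease status was the largest difference among the libraries. The first principal component held 42.3% of the variance and placed naive libraries between -86.6 and -80.9 and untreated PIA libraries between 33.8 and 63.1. Healthy RTD-1 libraries lay at the naive end, between -99.3 and -90.6. The second component held 8.08% and separated 3 saline libraries from every other arthritic library. These were replicate 2 of day 1 (99.1), replicate 4 of day 3 (91.1) and replicate 1 of day 5 (81.4), while the highest other arthritic library reached 9.46. The same 3 were deeper than the other arthritic libraries, as were all 10 healthy RTD-1 libraries, and they are called the deeper saline libraries from here on. The gene with the most reads in each of the 3, ENSRNOG00000047746, was singled out after its values were seen. It took between 7.59% and 10.1% of their reads at most 0.389% in the other arthritic libraries, and at most 0.0410% in the healthy RTD-1 libraries.

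**Figure D1:**
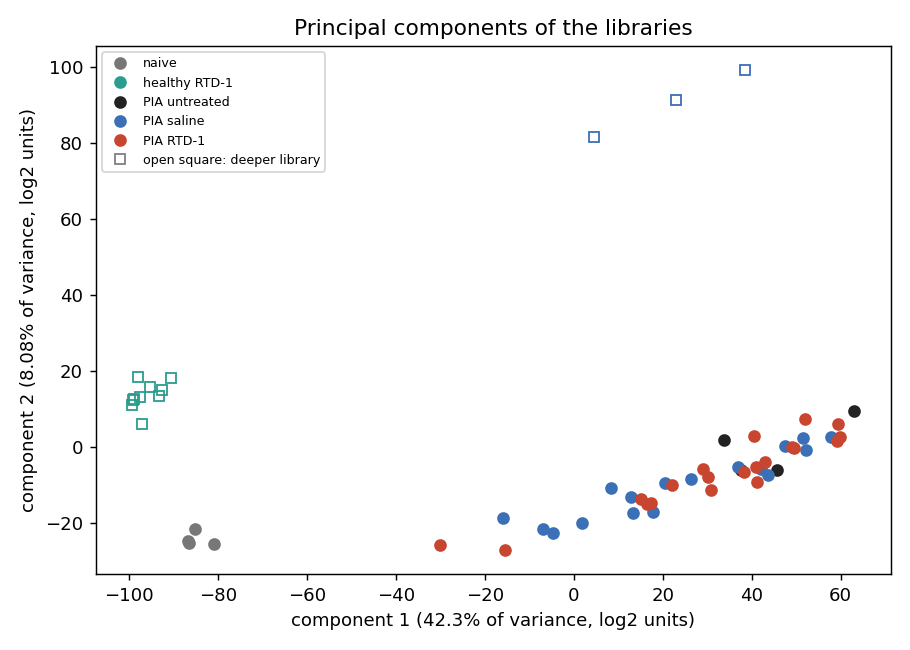
Each point is 1 library, placed by its first component (42.3% of the variance, log2 units) and second component (8.08%, log2 units), coloured by group, with open squares for the deeper libraries. Naive and healthy RTD-1 libraries sit at the left, arthritic libraries at the centre and right, and 3 deeper saline libraries lie above 81.

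The first comparison asked which genes differed between arthritic and naive synovium. Of 13062 genes tested, 5130 differed between untreated PIA and naive tissue, 3637 higher and 1493 lower in PIA (limma, Benjamini-Hochberg adjusted p under 0.05). Among them 3219 also changed at least 2-fold, 2035 upward and 1184 downward. The file gives no names for its identifiers, so only the genes with the largest folds are given. ENSRNOG00000002548 rose from 13.4 ± 11.2 normalized reads in naive tissue (SD, n = 4) to 13540 ± 7898 in PIA (SD, n = 4), a log2 fold change of 9.88 (SE 0.637, limma adjusted p = 1.31e-16). ENSRNOG00000008478 rose from 9.20 ± 14.8 to 919.1 ± 437 (SD, n = 4 each), a log2 fold change of 7.47 (SE 1.18, limma adjusted p = 1.45e-06). ENSRNOG00000013552 was among the abundant transcripts of naive tissue, at 26088 ± 6117, and stood at 23.4 ± 14.5 in PIA (SD, n = 4 each), a log2 fold change of -10.18 (SE 1.45, limma adjusted p = 1.57e-07). ENSRNOG00000013128 went from 482.5 ± 180 to 3.60 ± 3.60 (SD, n = 4 each), a log2 fold change of -7.11 (SE 0.856, limma adjusted p = 3.44e-09). Folds are on the log2(normalized reads + 1) scale, which understates changes of low values. The median gene was 0.28 log2 higher in PIA as deposited and -0.01 with TMM factors, which gave 2531 genes higher and 2626 lower.

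**Figure D2:**
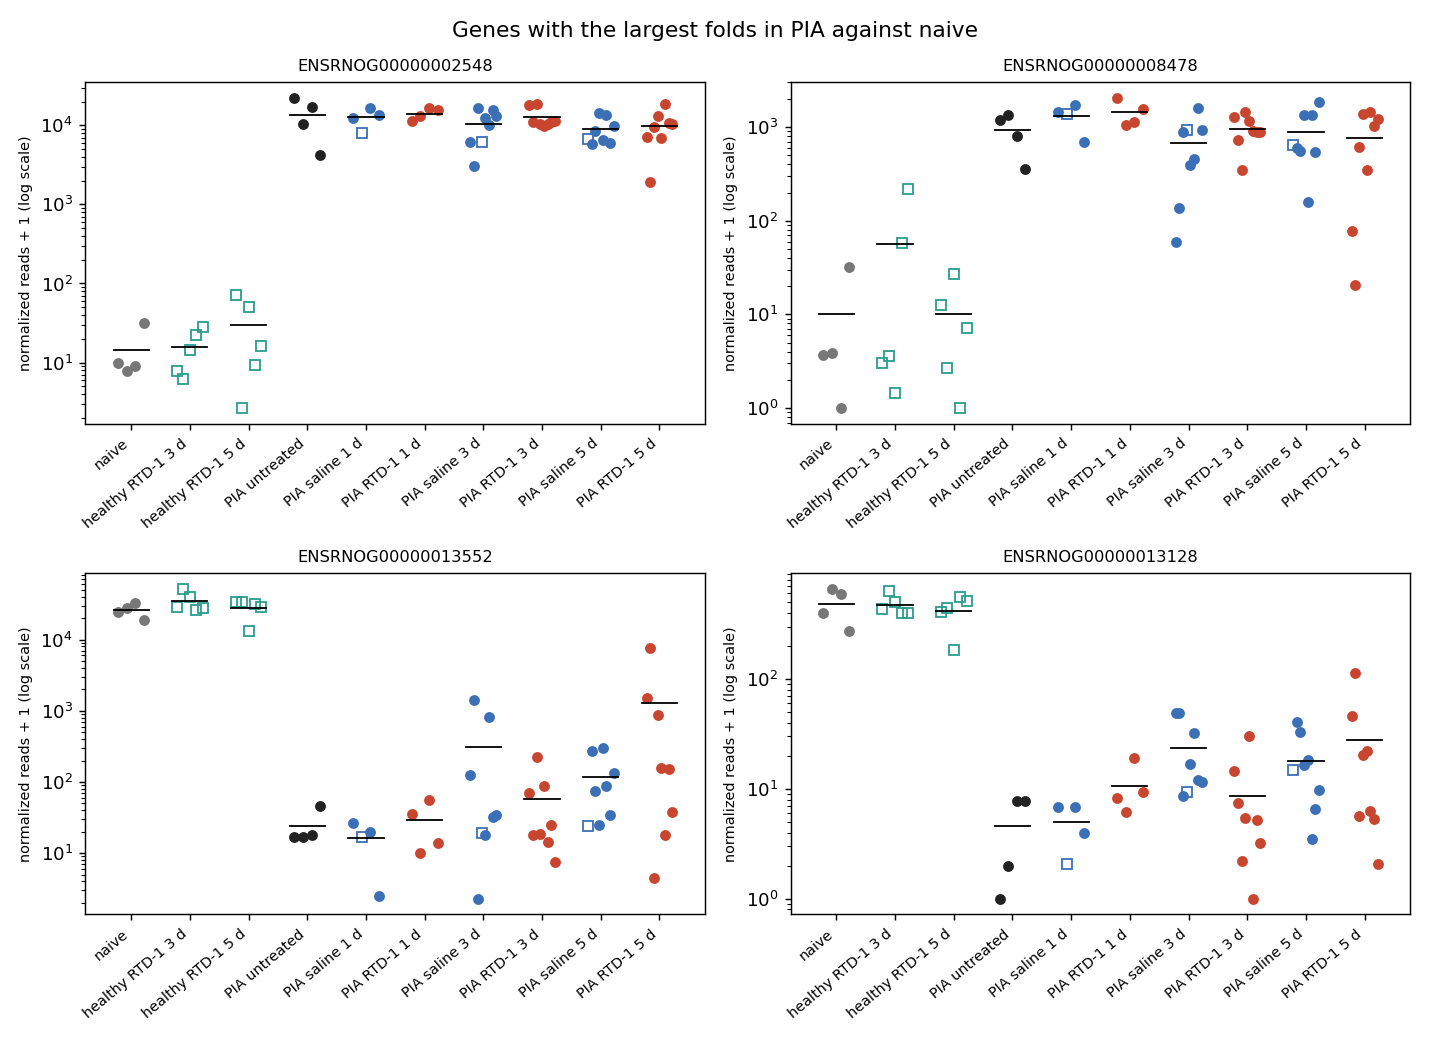
Normalized reads plus 1 (log scale) of the 4 genes with the largest folds between PIA and naive tissue, 1 point per library, with group means as lines and open squares for the deeper libraries. ENSRNOG00000002548 and ENSRNOG00000008478 were high in arthritic groups, and ENSRNOG00000013552 and ENSRNOG00000013128 in naive and healthy RTD-1 groups.

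The central comparison asked whether RTD-1 changed synovial expression in arthritic rats relative to saline of the same duration. Almost no gene passed the test. limma called 0 genes on day 1, 1 gene on day 3 and 0 genes on day 5, and 0 genes when the effect was averaged over the days. At an unadjusted p under 0.05 the numbers were 612, 1010, 470 and 760 of 13062 genes. With replicates 1 to 4 only they were 1468 on day 3 and 2205 on day 5, with median changes of 0.161 and -0.239 log2. With replicates 5 to 8 only they were 1538 and 912, with medians of the opposite sign, -0.215 and 0.166. Opposite differences in the 2 sets may therefore have lowered the pooled numbers. In limma voom on recovered reads, an added test, no gene passed on any day or in the average. Without the deeper saline libraries the limma counts were again 0, 1, 0 and 0, and without RTD-1 replicate 1 the day 1 count was 1. None of the 4 genes named above passed the test on any day, with a lowest limma adjusted p of 0.387. ENSRNOG00000002548 stood at 12590 ± 3508 after 3 days of RTD-1 and 10439 ± 4925 after 3 days of saline (SD, n = 8 each), and at 9834 ± 4935 and 8880 ± 3394 on day 5 (SD, n = 8 each). On simulated data the test recovered 50% of 2-fold changes on day 1, 72% on day 3 and 70% on day 5. It recovered 90%, 96% and 94% of 4-fold changes on those days, with 8, 14 and 6 false calls, so small effects could have been missed. Simulated genes varied independently of each other, without differences shared by many genes of a library, so these figures may overstate recovery.

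The gene called on day 3, ENSRNOG00000055829, was chosen after its values were seen. It had 1.14 ± 1.41 normalized reads after RTD-1 and 8.28 ± 4.52 after saline (SD, n = 8 each), a log2 fold change of -2.23 (SE 0.417, limma adjusted p = 0.0210). Naive tissue held 99.2 ± 23.9 and untreated PIA 4.17 ± 5.62 (SD, n = 4 each). RTD-1 groups of day 1 and day 5 held 9.34 ± 6.96 (SD, n = 4) and 7.66 ± 6.51 (SD, n = 8), and all arthritic groups were near the floor of 0 reads. It was also the 1 gene for which the RTD-1 effect differed between day 3 and day 1, by -3.91 log2 (SE 0.723, limma adjusted p = 0.0161). No gene differed for day 5 against day 1 (627 at an unadjusted p under 0.05) or day 5 against day 3 (917). For day 5 against day 3 the count was 179 with replicates 1 to 4 only (6 higher and 173 lower), 0 with replicates 5 to 8 only, and 7 with TMM factors and without the deeper saline libraries. The day 3 count was 0 with pseudocount 8, a filter of 50 normalized reads, array weights, only the groups compared in the fit or replicates 1 to 4 only. It fell to 0 without RTD-1 replicate 6 or 8, or without saline replicate 2, 6 or 8. It rose to 5, 3, 2 and 4 without RTD-1 replicates 1, 3, 4 and 5, and to 11 and 3 without saline replicates 3 and 7. The day 3 against day 1 count fell to 0 without day 1 RTD-1 replicate 1 or day 1 saline replicate 4. It rose to 2 without day 1 saline replicate 2, day 3 RTD-1 replicate 1 or day 3 saline replicates 6, 7 or 8, and to 3 without day 1 saline replicate 1 or day 3 RTD-1 replicate 7.

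**Figure D3:**
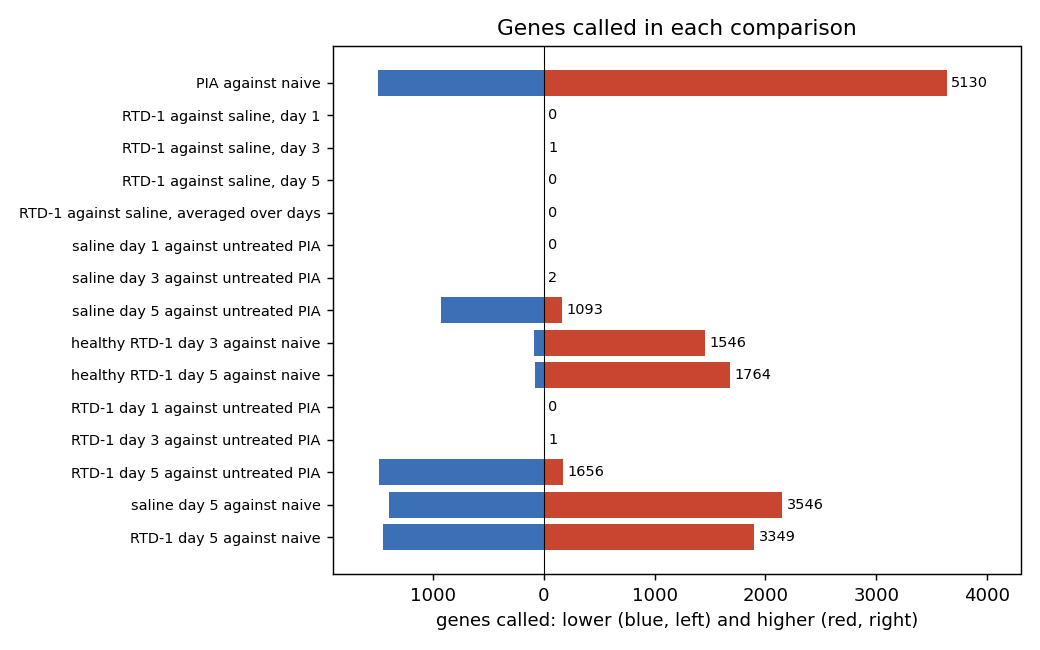
Bars give the number of genes called in each comparison, with higher genes to the right, lower genes to the left and the total beside each bar. PIA against naive has 5130, and the RTD-1 against saline comparisons have between 0 and 1.

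To ask whether RTD-1 moved the tissue back toward the naive state, each library was scored on the 3219 signature genes. Naive libraries were set at 0% and untreated PIA, at 4.18 log2, at 100%. Scored with signatures fitted without them, naive libraries averaged 0.27 log2 and PIA libraries 3.99. After 1 day the score was 100.9% ± 4.85 with RTD-1 and 100.5% ± 1.95 with saline (SD, n = 4 each). After 3 days it was 91.1% ± 9.61 with RTD-1 and 77.0% ± 14.8 with saline (SD, n = 8 each). After 5 days it was 70.7% ± 16.6 with RTD-1 and 72.2% ± 12.6 with saline (SD, n = 8 each). RTD-1 minus saline was 0.350% of the distance on day 1 (95% interval -8.36 to 6.74, two-sided exact permutation p = 0.886). On day 3 it was 14.1%, with the RTD-1 libraries farther from naive (interval 0.874 to 27.6, exact permutation p = 0.0382, 0.115 after adjustment over the 3 days). On day 5 it was -1.44% (interval -17.6 to 14.4, exact permutation p = 0.848), made up of -0.48 log2 in replicates 1 to 4 and 0.35 log2 in replicates 5 to 8, neither of which passed an exact permutation test. The RTD-1 and saline labels behind these differences were taken from the sample titles and were not checked against expression. No day passed the adjusted threshold. On each day 0 signature genes were called as moved back by RTD-1, which adds little, since limma called at most 1 gene between the arms. The difference of the day 3 and day 1 effects, 0.58 log2, had a permutation p of 0.0297, or 0.0891 after adjustment over 3 such tests. Day 5 minus day 3 was -0.65 log2 (permutation p = 0.0950, adjusted 0.142) and day 5 minus day 1 was -0.08 (permutation p = 0.816, adjusted 0.816). At day 3 leaving out RTD-1 replicate 5 or saline replicate 3 brought the adjusted exact permutation p to 0.0476 or 0.0448, with RTD-1 higher.

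**Figure D4:**
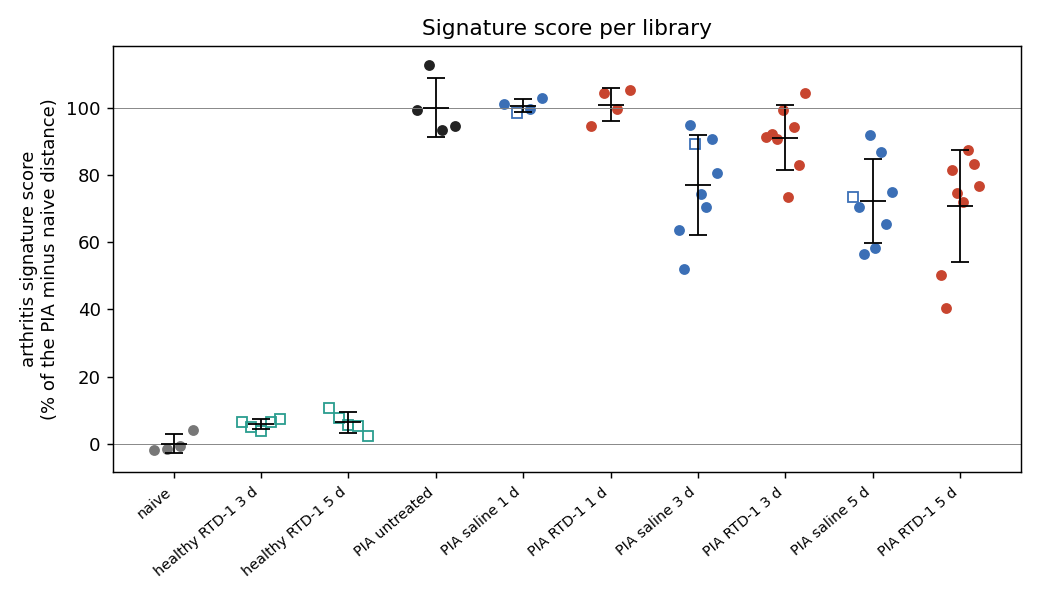
Each point is the signature score of 1 library as a percent of the distance from naive (0) to untreated PIA (100), with group means and SD as bars and open squares for the deeper libraries. Scores lie near 100 on day 1 and fall to 72.2 with saline and 70.7 with RTD-1 on day 5.

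The time course in each arm was compared with untreated PIA. Against untreated PIA, limma called 0 genes after 1 day of saline (699 at an unadjusted p under 0.05), 2 after 3 days and 1093 after 5 days, 167 higher and 926 lower. The 2 genes of day 3, named after their values were seen, were ENSRNOG00000013946 (117.0 ± 24.7 after saline, SD, n = 8, and 239.9 ± 28.7 in PIA, SD, n = 4) and ENSRNOG00000020465 (73.2 ± 22.2 and 171.0 ± 40.9, same groups). With RTD-1, in comparisons added after the data were seen, the counts were 0 on day 1 (273 at an unadjusted p under 0.05), 1 on day 3 and 1656 on day 5, 174 higher and 1482 lower. With TMM factors the day 5 splits became 714 higher and 569 lower for saline and 681 higher and 599 lower for RTD-1. Both sets share the PIA libraries, so the direct test between arms, with 0 calls on day 5, is the one that compares them. On scores fitted without the library being scored, day 5 differed from PIA by -0.97 log2 with saline (approximate permutation p = 0.0141). With RTD-1 the difference was -1.03 (approximate permutation p = 0.0202), and both p-values were 0.0808 after adjustment over 8 tests. The day 5 saline count was 501, 250 and 274 without PIA replicates 1, 2 and 4, and 2002, 727, 541 and 691 without saline replicates 4, 5, 7 and 8. It was 158 with only the groups compared in the fit, 93 with replicates 1 to 4 only, where the direction turned to 62 higher and 31 lower, and 2933 with replicates 5 to 8 only (141 higher and 2792 lower). With a replicate block it was 4, all higher, but PIA has no replicates 5 to 8, so the block in effect compared replicates 1 to 4 only. The day 5 RTD-1 count was 810, 615 and 549 without PIA replicates 1, 2 and 4, and 1026 without RTD-1 replicate 1, and it was 2610 with replicates 1 to 4 only and 547 with replicates 5 to 8 only. With a replicate block, which again rested on replicates 1 to 4, it was 536, and with a term for replicates 1 to 4 against 5 to 8 it was 1011. Leaving out any 1 of the 12 libraries moved the day 3 saline count, to between 0 and 50. That count was 85 with TMM factors, where the direction turned to 57 higher and 28 lower, 272 (170 higher and 102 lower) when the deeper saline libraries were also left out, 119 with replicates 5 to 8 only and 589 with array weights. Leaving out 7 of 12 moved the day 3 RTD-1 count, to between 0 and 8. With replicates 5 to 8 only that count was 150 (4 higher and 146 lower).

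At day 5 both arms were still far from naive tissue. In added comparisons, limma called 3546 genes between saline day 5 and naive, 2151 higher and 1395 lower, and 3349 between RTD-1 day 5 and naive, 1898 higher and 1451 lower. With a replicate block the counts were 2933 for saline and 1786 for RTD-1. ENSRNOG00000002548 stood at 8880 ± 3394 with saline and 9834 ± 4935 with RTD-1 (SD, n = 8 each), against 13.4 ± 11.2 in naive tissue (SD, n = 4). ENSRNOG00000013552 was at 118.0 ± 110 with saline and 1286 ± 2573 with RTD-1 (SD, n = 8 each), and RTD-1 replicate 2 alone held 7510.

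The last comparison asked what RTD-1 did without arthritis. Healthy rats given RTD-1 lay at the naive end of the arthritis signature, at 5.89% ± 1.41 on day 3 and 6.33% ± 3.12 on day 5 (SD, n = 5 each). Naive libraries define 0% there, but averaged 0.27 log2 when each was scored with a signature fitted without it. Healthy RTD-1 libraries averaged 0.25 log2 on day 3 and 0.26 on day 5, so the 5.89% and 6.33% are no distance from naive. On scores fitted without the library being scored, they differed from naive by -0.03 log2 on day 3 (interval -0.24 to 0.11, approximate permutation p = 0.857). On day 5 the difference was -0.01 (interval -0.29 to 0.22, approximate permutation p = 0.921). Between these groups limma called 1546 genes on day 3, 1456 higher and 90 lower, and 1764 on day 5, 1684 higher and 80 lower. With TMM factors the counts were 673 (367 higher and 306 lower) and 617 (362 higher and 255 lower), and with array weights they were 3776 and 4350. Every healthy RTD-1 library was deeper than every naive one, and the genes called on day 3 with TMM factors differed in the same direction between the deeper saline libraries and other saline libraries in 92.1% of cases. Without naive replicates 2, 3 and 4 the day 3 count was 771, 2425 and 624, and without healthy RTD-1 replicate 1 it was 980. On day 5 it was 1143, 810, 2763 and 803 without naive replicates 1, 2, 3 and 4, and 1158 and 1142 without healthy RTD-1 replicates 2 and 4.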

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

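Tests of scaling and depth in the healthy libraries, and of the deeper saline library in the day 3 score, were chosen after the results were seen; the shared-direction test, both tests of the second component and the test of the shallowest libraries were fixed before theirs.

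Healthy RTD-1 libraries differed from naive in 1546 genes on day 3, almost all higher. With the deposited scaling the median gene was 0.30 log2 higher on day 3 and 0.34 on day 5, so the excess went with a library-wide shift. Reads in genes made up 28.5% to 41.6% of the factor in naive libraries and 39.2% to 43.1% in healthy day 3 libraries. Whether scaling alone produced the shift and the excess stays open, because TMM factors centre the libraries and so fix the balance (54.5% of calls higher). Scaling is not the whole cause of the calls, since 673 were left with TMM factors and the highest of the other splits gave 204. After thinning 1294 genes were called, so depth does not account for most of the 1546. Thinning kept the deposited scaling and was not combined with TMM factors. It therefore cannot say whether depth underlies the 673 genes. Of the 673 genes, 92.1% differed in the same direction between the 3 deeper saline libraries and the other saline libraries, which share no library with this comparison, and the 3 taken singly gave between 84.0% and 88.7%, while the 17 other saline libraries taken singly gave between 43.8% and 57.4%. The sharing was not complete, since ENSRNOG00000047746 took at least 7.59% of reads in the deeper saline libraries and at most 0.0410% in healthy RTD-1 libraries, and the row without an identifier, raised in healthy RTD-1 libraries, was at 36.5, 9.29 and 13.5 normalized reads in the deeper saline libraries. A library or sequencing difference shared in part by the deeper libraries may underlie some of this contrast, and an effect of RTD-1 or of injection stays open and untested, because no saline-treated healthy group was analysed.

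The 3 deeper saline libraries stood far above the others of their groups on the second component, at 99.1 on day 1, 91.1 on day 3 and 81.4 on day 5, where the others reached at most 2.50, 0.182 and -5.30. Reads in genes were also far higher in the day 3 library (5.73 megareads, others up to 2.20) and the day 5 library (6.42 megareads, others up to 2.40). Depth alone is argued against: after thinning, the lowest of the 3 lay 76.8 above the highest other arthritic library, against an SD of 9.17 among the others. The gene with the most reads is not the whole cause either, since the gap was 71.3 without ENSRNOG00000047746. A different preparation or run, or a difference between the animals, stays open, and no biological explanation was tested.

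On day 3 the signature score was higher with RTD-1 than with saline by 0.59 log2 (exact permutation p = 0.0382, 0.115 after adjustment). The 2 shallowest RTD-1 libraries are not the whole cause, as the difference was 0.47 without them. The deeper saline library scored 3.74 log2, above the saline mean of 3.22, and so narrowed the difference. Leaving that library out could only widen the difference, to 0.66, so this was not a test that could have gone the other way. Chance stays open, since the adjusted value missed the threshold.

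ENSRNOG00000055829 differed in its RTD-1 effect between day 3 and day 1 by -3.91 log2 in limma (adjusted p = 0.0161), at levels near the floor. Among the genes with the largest folds, single libraries stood apart: ENSRNOG00000002548 in naive replicate 4 (30.2 normalized reads, others up to 8.89), and ENSRNOG00000008478 in naive replicate 4 (31.2, others up to 2.88) and healthy RTD-1 day 3 replicate 5 (217.5, others up to 57.0). ENSRNOG00000013552 stood apart in healthy RTD-1 day 5 replicate 3 (13149, others from 28328), PIA replicate 4 (45.1, others up to 16.7), RTD-1 day 3 replicate 3 (223.2, others up to 86.4) and RTD-1 day 5 replicate 2 (7510, others up to 1533). ENSRNOG00000013128 stood apart in RTD-1 day 3 replicate 5 (29.3, others up to 13.6) and RTD-1 day 5 replicate 2 (112.3, others up to 45.3). Over 8 measures in 10 groups, 14 of 80 checks found such a library. Chance gives about 4 only if values within a group are normally distributed. That was not tested, and the reads of the genes were not log-transformed, so the excess cannot be judged. The checks are also not independent, since the same libraries recur. The row without an identifier was higher in healthy RTD-1 libraries, at 273.3 ± 64.5 normalized reads on day 3 and 218.7 ± 50.4 on day 5 (SD, n = 5 each), than in naive libraries, at 49.4 ± 11.7 (SD, n = 4).

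Other splits of the same libraries show how often exchanged labels call as many genes. At most 100 splits were used for each comparison, with no adjustment over the comparisons. For PIA against naive only the real split reached 5130 genes (1 of 35 splits as large, highest other 2932). The same held for healthy RTD-1 day 3 (1546, 1 of 100, highest other 393). Against naive it held for saline day 5 (3546, 1 of 100, highest other 1968) and RTD-1 day 5 (3349, 1 of 100, highest other 1733). These values argue against chance. RTD-1 day 5 against PIA was less firm (1656, 1 of 100, highest other 796), since its count fell to 549 without PIA replicate 4. For healthy RTD-1 day 5 (1764 genes, 2 of 100, highest other 1788), and for saline against PIA on day 5 (1093 genes, 4 of 100, highest other 2507) and day 3 (2 genes, 4 of 100, highest other 382) few splits were as large, but others called more genes and the counts moved with single libraries, so chance is not firmly excluded. It cannot be excluded for RTD-1 against saline on day 3 (1 gene, 15 of 100, highest other 2841), the day 3 against day 1 effect (1 gene, 10 of 100, highest other 110) or RTD-1 day 3 against PIA (1 gene, 38 of 100, highest other 987). Where 0 genes were called the splits say nothing, since every split gives at least 0: 35 of 35 for day 1 of RTD-1 against saline, of saline against PIA and of RTD-1 against PIA (highest other 1 each), and 100 of 100 for day 5 of RTD-1 against saline (highest other 435), the average over days (highest other 4), day 5 against day 1 (highest other 1) and day 5 against day 3 (highest other 1220). The highest splits between arms, with 2841 genes on day 3 and 435 on day 5, did not follow the treatment labels, and what set them apart was not tested.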

How the results depend on the processing

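Voom, thinning, removal of the deeper saline libraries and score tests on replicates 1 to 4 or 5 to 8 were chosen after seeing the data; edgeR and DESeq2 on the recovered reads were planned but not run, voom being the test of those reads, and the gene list alternatives were not run because no identifier had a symbol. PIA against naive gave between 4152 and 6178 calls in the alternatives run, and its 4 named genes kept direction and significance in all 19 settings each. RTD-1 against saline averaged over days stayed at 0 calls throughout. The cause of the changes below was not tested, except that left-out libraries and restricted replicates mean fewer samples.

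The day 3 score difference stayed positive in all 26 alternatives (0.27 to 0.85 log2). Its adjusted exact permutation p, the planned criterion, was under 0.05 in 2 of them, both with a library left out, and ranged from 0.0448 to 0.600. Its unadjusted exact permutation p was 0.05 or more in 14 of the 26, 10 of them with a library left out, among them pseudocount 8 (0.0539), the replicate block (0.0781) and replicates 1 to 4 (0.200) or 5 to 8 (0.257) alone. The near-zero day 1 difference turned to -0.0064 with the stricter signature and -0.0150 without the deeper saline libraries, and day 5 to 0.35 with replicates 5 to 8 only, against -0.48 with replicates 1 to 4 only. With 1 library left out, day 1 ran from -0.0449 to 0.102, day 3 from 0.441 to 0.699 and day 5 from -0.160 to 0.120.

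Replicate numbers gave no clear pairing of the samples: same-number correlations were not all above 0.1 in any comparison, and no comparison had more than 3 of 8 or 2 of 4 samples that matched their own number best. The mean same-number correlation was 0.071 in RTD-1 against saline on day 5 (other numbers -0.010). In PIA against naive it was -0.040 (other numbers 0.013). Weak pairing stays open. In comparisons with PIA or naive, libraries numbered 5 or more had no partner, so there the block in effect compared replicates 1 to 4 only. The median gene of saline day 5 against PIA was -0.0516 log2 both with the block and with replicates 1 to 4 only. Changes of those counts under the block therefore do not show an effect of pairing. With the replicate block, RTD-1 against saline on day 3, saline day 3 and RTD-1 day 3 against PIA, and day 3 against day 1 gave 0 calls, saline day 1 against PIA 1, saline day 5 against PIA 4 (all higher), RTD-1 day 5 against PIA 536, RTD-1 day 5 against naive 1786 and healthy RTD-1 day 3 2409.

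RTD-1 against saline on day 3 gave 0 calls with pseudocount 8, 50 normalized reads, array weights, own groups, voom and replicates 1 to 4, 2 with TMM factors with or without the deeper saline libraries, and 3 with the replicate-number term; day 5 gave 1 with replicates 1 to 4. Day 3 against day 1 gave 0 with pseudocount 8, quantile normalization, array weights, own groups, voom, thinning and without the deeper saline libraries (TMM factors or not), and 2 with pseudocount 0.5 and the replicate-number term. Day 5 against day 1 gave 1 with array weights and voom. Day 5 against day 3 gave 1 with no filter, TMM factors and array weights, 2 with quantile normalization, 7 with TMM factors without the deeper saline libraries and 179 with replicates 1 to 4. Saline against PIA gave 1 on day 1 with own groups. On day 3 it gave 16 with pseudocount 8, 1 with no filter and with replicates 1 to 4, 85 with TMM factors (57 higher), 88 with quantile normalization (59 higher), 589 with array weights, 0 with own groups and the replicate-number term, 119 with replicates 5 to 8, 68 with voom, and without the deeper saline libraries 21, or 272 with TMM factors. On day 5 it gave 1762 with array weights, 158 with own groups, 630 with the replicate-number term, 93 with replicates 1 to 4 (62 higher and 31 lower) and 2933 with replicates 5 to 8. RTD-1 against PIA gave on day 3 2 with TMM factors and array weights, 3 with quantile normalization, 0 with own groups, the replicate-number term, replicates 1 to 4, voom and thinning, and 150 with replicates 5 to 8; on day 5 it gave 2561 with array weights, 1011 with the replicate-number term, 2610 with replicates 1 to 4 and 547 with replicates 5 to 8. Healthy RTD-1 against naive gave 673 (day 3) and 617 (day 5) with TMM factors, 787 and 700 with quantile normalization, and 3776 and 4350 with array weights. TMM factors split day 5 against naive into 2199 higher and 2106 lower with saline and 2166 and 2048 with RTD-1.

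With 1 library left out, counts ran from 0 to 1 for RTD-1 against saline on day 1, 0 to 11 on day 3, 0 to 3 for day 3 against day 1, 0 to 50 for saline day 3 and 250 to 2002 for saline day 5 against PIA, 0 to 8 and 549 to 1934 for RTD-1 day 3 and day 5 against PIA, 624 to 2425 for healthy RTD-1 day 3 and 803 to 2763 for day 5. Depth limits low genes most in the libraries with 464693 and 935255 reads.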
